A study of Equus caballus with 34 samples.

How the data were processed

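RNA from granulosa cells (GC) and theca wall (TW) of equine dominant follicles was measured on single-colour Agilent arrays, 1 array per sample. The labels place each of the 34 arrays in a cell type and in 1 of 3 stages, early dominant (ED), late dominant (LD) and preovulatory (PO). There were 5 arrays in each GC stage, 5 for TW ED, 9 for TW LD and 5 for TW PO. The design text speaks of biological replicates and of stage comparisons within each cell type with 5 samples per group. The labels do not say which 5 of the 9 TW LD samples were meant, so all 9 were used. Replicates carry numbers given in accession order, which only name arrays, although GC arrays of 1 number share a slide, as do TW ED and TW PO arrays. Whether GC and TW samples came from the same follicles is not given in the sources used here.

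Per the labels' protocols, RNA was extracted with TRIzol, and RNA with an integrity number above 7.0 (500 ng) was reverse transcribed from an oligo(dT) primer with a T7 promoter, amplified as antisense RNA and labelled with Cy3. Per the file headers, the spot intensity values come from images scanned on an Axon GenePix scanner and read with Agilent Feature Extraction 9.5.3.1, while the submitters' processing notes name version 9.1. The processed intensity in these deposited files has the local background subtracted and spatial trends removed by Feature Extraction, with a substitute value for very dim spots, and no scaling between arrays. The files also carry deposited flags for spots well above background, saturated spots and spots whose pixels scatter. The deposited value table holds log2 values with no stated processing. Compared with the scanner files, each of its columns correlated at r = 0.999995 with quantile-normalized log2 mean signal, without background subtraction, and differed from it by at most 0.0329. Every column has a median of 7.29, so its scale and centring are settled by that comparison.

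On each array, 43803 spots outside the controls entered. From 64.3% to 82.5% of them (median 72.9%) were well above background, 54 to 375 were saturated (median 223), and the 75th percentile of the processed signal lay between 785 and 2062 (median 1388). The coefficient of variation of repeated probes was 3.36% to 6.18% except on the 4 arrays of slide 7 (TW LD 6, TW LD 7, TW ED 4 and TW PO 4), where it was 16.2% to 28.3%. Those 4 arrays also held 1285 to 1718 spots with an outlier flag, against 69 to 593 elsewhere. The number of arrays limits the precision of every value.

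The main values were log2 of the processed signal minus each array's 75th percentile over non-control probes. Control spots and outlier-flagged spots were left out, saturated spots were kept, and spots of 1 probe were averaged. A probe entered a fit if it was well above background on at least 5 of the arrays fitted. A gene was represented by its probe with the highest mean over all 34 arrays, and a probe with no gene name stood as a feature of its own. Of 43603 probes, 22149 received a symbol (12113 distinct symbols). Names came from a gene number in the file's name (16616 probes), a symbol in the file (4752), a RefSeq accession (829), a gene number in the description (640), a protein name in the description (331) or a synonym (65), matched to a table of RefSeq genes of assembly TB-T2T that served for names only. No symbol was found for 20370 probes, and 1084 had only a locus number.

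Stage changes were fitted with limma (lmFit and eBayes) on the arrays of 1 cell type, with a mean per stage. The difference between cell types and the difference of stage changes between cell types (the interaction) were fitted on all 34 arrays with 6 group means. Features were called at a Benjamini-Hochberg adjusted p under 0.05 over all features of a fit, and every adjusted p of a gene comes from these limma fits. Where all arrays of a group lay below background, a fold is given as "at least": the brighter group's mean was set against, for each dim array, the higher of the lowest signal well above background and the probe's own signal. Where only some arrays of a group were well above background, a fold or log2 change against it is not exact.

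A set of 26 gene lists was fixed before the data were examined: granulosa, theca, endothelial, smooth muscle and pericyte, and leukocyte markers, red blood cell and oocyte genes, steroid synthesis, cholesterol synthesis and uptake, gonadotropin receptors with inhibins and hormone receptors, the insulin-like growth factor system, the ovulatory cascade, prostaglandin metabolism, matrix proteases and inhibitors, collagens and structural matrix, cell division, cell cycle inhibitors with D cyclins, angiogenic factors, cytokines with chemokines and adhesion molecules, immediate early and stress genes, glycolysis and hypoxia, the mitochondrial respiratory chain, endoplasmic reticulum stress, antioxidant genes, cell junctions, and apoptosis regulators. Lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01 between genes, and p was adjusted over all 98 list tests of the 4 stage comparisons. The same tests were run with a correlation estimated for each list, and with fry, which asks whether a list's genes move on balance one way and does not compare them with other genes.

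Genes named in the text follow a rule that was also fixed before the data were examined. For each stage comparison it takes the 8 highest and 8 lowest called genes with a symbol that were well above background on every array of the higher group, the 2 called members with the largest change of each list that camera called, and 10 genes always named (FSHR, LHCGR, STAR, CYP11A1, CYP17A1, CYP19A1, INHA, INHBA, PTGS2 and VEGFA). It takes 4 genes per direction for an interaction, and 5 per direction plus the granulosa and theca markers for the difference between cell types. Further list members are cited as examples of their list.

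The alternatives fixed before the data were examined were normexp background correction (offset 50), quantile normalization, median centring, the deposited values, no filter or a stricter filter on dim probes, the mean of a gene's probes, slide as a random or fixed block, array weights, a further threshold of 2-fold, other sets of arrays in the fit, other sets of TW LD arrays, and each array left out in turn. Slides were tested as batches: the 34 arrays lay on 10 slides, each with all 3 stages of a cell type, and 2 slides also held a TW LD array beside the GC arrays. Leaving out slide 7, leaving out GC LD 3 with GC PO 2, and median centring for the list tests were chosen after seeing the data, as were the comparisons of each list with features of the same brightness (10 bins) and with the median of all features under each scaling.

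Each test was first run on simulated data in which 200 features were changed. Of 100 features changed by log2 1 and 100 changed by log2 2, the test recovered 11 and 62 in GC LD minus ED, and 6 and 62 in GC PO minus LD (24759 features each). It recovered 58 and 90 in TW LD minus ED, and 45 and 86 in TW PO minus LD (26896 features each). For the interactions it recovered 10 and 55 (LD minus ED) and 6 and 44 (PO minus LD), and for GC minus TW 71 and 96 (27678 features each). False calls made up 7.59%, 5.56%, 4.52%, 2.24%, 1.52%, 1.96% and 5.65% of the calls, in the order given. A cell division list shifted by log2 0.5 was called in each of the 4 simulated stage comparisons, with 0 other lists called. The simulated features were drawn independently of each other, so this does not check the list test for genes that move together. On the real arrays, reassigned stages gave a median of 26 list calls against the real 43. The analysis used R 4.3.3, limma 3.58.1, the data.table package (1.17.8) and jsonlite 2.0.0.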

Results

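The arrays compared 2 layers of the equine dominant follicle, the granulosa cells (GC) that line its cavity and the vascularised theca wall (TW) around them, at 3 stages. GC had 5 arrays each at the early dominant (ED), late dominant (LD) and preovulatory (PO) stage, and TW had 5 ED, 9 LD and 5 PO arrays. Between 64.3% and 82.5% of the 43803 spots on an array were well above background. Changes are log2 differences with the standard error (SE) of the limma fit, and n is the number of arrays in the groups compared. Counts "beyond" give the arrays of the first group that lay outside the range of the second in the direction of the change.

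The comparison of GC with TW, averaged over the stages, asked which transcripts set the layers apart (15 GC and 19 TW arrays). GC held 91.3-fold more CDH2, the gene of N-cadherin (log2 6.51 ± 0.50 SE, adjusted p = 1.38e-12, all 15 GC arrays beyond), and 72.6-fold more PTHLH, the gene of parathyroid hormone-related protein (6.18 ± 0.46 SE). MAB21L2 (63.3-fold), SEMA3E (60.6-fold, well above background on 2 of 19 TW arrays) and KCNV1 (52.9-fold) followed. FSHR, the FSH receptor, was 44.1-fold higher in GC (5.46 ± 0.59 SE, 11 of 15 arrays beyond), and CYP19A1, the aromatase that makes estrogens, 29.5-fold (4.88 ± 0.54 SE, 12 of 15 beyond). TW held 186-fold more TM4SF18 (log2 −7.54 ± 0.39 SE, adjusted p = 1.45e-16), which was well above background on 4 of 15 GC arrays, so the size is not exact. LRRC17 (182-fold), TCF21 (132-fold), ECSCR, an endothelial membrane protein (128-fold), and SNAI2 (122-fold, 3 of 15 GC arrays well above background) were also higher in TW. Of 19 TW arrays, 9 were well above background for MAB21L2 and 6 for KCNV1, FSHR and IHH, and of 15 GC arrays 11 were for ECSCR and LRRC17, 14 for TCF21 and FSHR, 10 for IHH and 5 for PDGFRA.

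Of 14471 features that differed among 27678 tested, 6214 were higher in GC and 8257 in TW. In the lists below, counts in brackets are adjusted over the list alone. Of 17 granulosa markers, 13 were higher in GC and 1 lower [15 and 1]. The higher ones besides CDH2, FSHR and CYP19A1 were NR5A2 (log2 4.77), INHBA (3.61), HSD17B1 (3.55), IHH (3.37), SLC35G1 (2.97), FST (2.48), INHA (2.28), INHBB (2.28), AMHR2 (1.08) and SERPINE2 (0.32). WT1 was higher in TW (−1.56), and GATM (0.79), GJA1 (0.06) and KRT18 (1.57) were not called. All 16 theca markers were higher in TW [16]. They included PDGFRA (−5.91), MGP (−5.84), ACTA2 (−5.46), LUM (−4.59), OGN (−4.34), NR2F2 (−4.32), THBS2 (−4.19), COL1A2 (−4.16) and DCN (−3.97), which encode mesenchymal and matrix proteins. They also included the hedgehog targets GLI1 (−3.22), PTCH1 (−1.94) and HHIP (−1.09), ALDH1A1 (−1.97), the androgen-making enzyme CYP17A1 (−2.23, saturated on 17 of 19 TW arrays) and the theca hormone INSL3 (−1.31).

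Markers of the vessels and immune cells that a theca wall holds were higher in TW as well. These were 21 of 23 endothelial markers [21] (TEK −6.06, EMCN −5.67), and all 18 smooth muscle and pericyte markers [18] (KCNMB1 −4.82). So were 29 of 31 leukocyte markers [29, with 1 higher in GC] (CD74 −5.64, C1QB −5.42) and 27 of 30 collagens and structural matrix genes against 1 higher in GC [27 and 1] (NID1 −5.73, COL6A1 −5.50). Cytokines, chemokines and adhesion genes had 28 of 34 higher in TW against 2 in GC [28 and 2] (CXCL12 −6.19, VCAM1 −6.08). GC had the higher level for 26 of 31 glycolysis and hypoxia genes against 2 [26 and 2] (ANKRD37 3.11, PDK1 2.60). It also had it for 16 of 24 endoplasmic reticulum stress genes against 1 [16 and 1] (HSPA5 0.89) and for 21 of 34 respiratory chain genes against 0 [21 and 0] (COX7C 1.13). Cholesterol genes went the other way, with 0 of 23 higher and 10 lower in GC [0 and 10]. Bracketed counts adjusted over the list alone follow the same layout for the rest, given as higher in GC and higher in TW: steroid synthesis 7 and 10 of 21 [7 and 11] with a median of −0.68 and a mean of 0.44, and gonadotropin and hormone receptors 10 and 4 of 20 [11 and 4]. Angiogenic factors had 6 and 16 of 27 [6 and 16], matrix proteases 4 and 13 of 25 [4 and 14], ovulatory cascade 9 and 8 of 26 [9 and 9] and prostaglandin genes 6 and 8 of 17 [7 and 8]. For cell division the counts were 7 and 3 of 61 [6 and 2], and for cell cycle inhibitors 8 and 4 of 17 [8 and 5]. Apoptosis regulators had 5 and 13 of 29 [5 and 13], cell junctions 3 and 9 of 21 [4 and 9] and immediate early genes 1 and 7 of 25 [1 and 5]. For insulin-like growth factor genes they were 4 and 7 of 16 [4 and 7], and for antioxidant genes 7 and 2 of 25 [7 and 0]. Oocyte genes had 2 and 3 of 6 [2 and 3] and red blood cell genes 1 and 1 of 4 [0 and 0].

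The share of differing features that were higher in GC depended on the scaling. It was 42.9% here, 60.8% with quantile normalization, 76.1% with median centring, 57.3% with normexp and 61.9% in the deposited values, which moved the median of all features by 0.24, 0.58, 0.24 and 0.20. Relative to that median, granulosa markers stayed between 1.93 and 2.75 and theca markers between −4.26 and −3.41 over the 5 scalings, glycolysis between 0.74 and 1.02, and the respiratory chain between −0.08 and 0.45, below 0 in 2 of them. Within slides 2 and 8, which hold both layers at the LD stage, granulosa markers differed by 3.66 and 4.09, theca markers by −3.12 and −3.92 and glycolysis by −0.14 and 0.92. The respiratory chain differed by −0.50 and 0.20. Only these 2 slides hold both layers, so cell type and slide were largely confounded in the comparison of GC with TW. Of the features called in it, 76.6% on slide 2 and 89.9% on slide 8 kept the pooled direction.

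The step from ED to LD in GC asked what changes as the dominant follicle grows on (5 and 5 arrays). Cell division genes, whose products build spindles and replicate DNA, lay lower at LD as a list, with a median log2 change of −2.25 over 61 genes (mean −2.07, camera adjusted p = 6.5e-27, and adjusted p = 0.508 with an estimated correlation). Not 1 member was called over all features, and 54 were lower when adjusted over the list alone. MCM6, a subunit of the replication helicase, was at −1.52 ± 0.37 SE (adjusted p = 0.20, all 5 LD arrays beyond). Ovulatory cascade genes lay higher as a list, with a median of 1.92 over 24 genes (adjusted p = 0.000239, and adjusted p = 0.508 with an estimated correlation), with 0 called and 11 higher adjusted over the list alone. PTX3 and HAS2, which build the matrix of the expanding cumulus, lay higher without passing the test (adjusted p = 0.16 each). PTX3 was at 6.73 ± 1.37 SE, and HAS2, not well above background on any ED array, was at least 45.7-fold higher.

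Of 24766 features, 1 was called, higher at LD. It was probe A_69_P004174, described as the 3′ untranslated part of the mRNA of the mitochondrial superoxide dismutase, named here after its values were seen. It was 9.70-fold higher (log2 3.28 ± 0.36 SE, adjusted p = 0.00483), well above background on 5 of 5 LD arrays and 1 of 5 ED arrays. The probe chosen for SOD2 itself was at 2.54 ± 0.65 SE (adjusted p = 0.20). The GC genes named in advance were not called. FSHR was at −2.98 ± 1.15 SE (adjusted p = 0.262), STAR, which delivers cholesterol to mitochondria, at 2.61 ± 1.06 SE (0.279) and CYP19A1 at −1.15 ± 0.65 SE (0.406). INHA was at −0.11 ± 0.24 SE (0.848) and INHBA at −0.14 ± 0.30 SE (0.842). CYP11A1 (−0.58 ± 0.67 SE, 0.688), CYP17A1 (−0.43 ± 0.87 SE, 0.835), LHCGR, the LH receptor (−0.53 ± 0.69 SE, 0.727), PTGS2 (−0.09 ± 0.89 SE, 0.969, with another probe at 0.25) and VEGFA (−0.37 ± 0.59 SE, 0.784) had adjusted p above 0.6.

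Camera called 12 of the 24 lists tested in this step, 8 higher and 4 lower, each with 0 members called over all features. None of the 12 was called with an estimated correlation (adjusted p = 0.508 except where given), and fry called cell division alone (adjusted p = 0.0474). Counts in brackets are adjusted over the list alone, higher and lower. The higher lists were the ovulatory cascade, immediate early genes (median 1.02 over 23 genes, adjusted p = 5.6e-06 [1 and 0]), and cholesterol synthesis and uptake (0.59 over 23, 1.5e-05 [0 and 0]). Also higher were smooth muscle markers (0.80 over 16, 0.00298 [0 and 0]), and matrix proteases (0.95 over 25, 0.0033 [3 and 0]). Leukocyte markers (0.87 over 28, 0.00618, adjusted p = 0.565 with an estimated correlation [4 and 0]), cytokines (0.66 over 22, 0.0134 [6 and 0]) and endothelial markers (0.67 over 13, 0.0191 [0 and 0]) were called higher too. The lower lists besides cell division were granulosa markers (−0.95 over 17, 0.0134 [0 and 0]) and endoplasmic reticulum stress genes (−0.21 over 23, 0.0191 [0 and 0]). So were gonadotropin receptors with inhibins and hormone receptors (−0.33 over 19, 0.0487, adjusted p = 0.544 with an estimated correlation [0 and 0]). Lists not called were glycolysis (0.06 [2 and 0]), cell junctions (−0.17 [0 and 1]), angiogenic factors (0.34 [1 and 1]) and, with [0 and 0] each, collagens (0.26), apoptosis (0.22), prostaglandins (0.22), cell cycle inhibitors (0.09), the respiratory chain (0.10) and theca markers (0.17). Median and mean differed in sign for antioxidant genes (−0.03 and 0.26, tested as higher [2 and 0]), steroid synthesis (−0.04 and 0.18, tested as higher [1 and 1]) and the insulin-like growth factor system (−0.24 and 0.14, tested as lower [0 and 0]). Oocyte genes (0.22 [1 and 1]) and red blood cell genes (0.58 [0 and 0]) had 4 members each and were not tested.

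GC LD arrays were spread widely, which limits this step. On a scale where the ED mean is 0 and the PO mean 1, they lay at 0.45, 0.59, 0.88, 0.13 and 0.01. The count of 1 became 8 without GC LD 4, 1261 without GC LD 5 and 1606 when all 34 arrays shared 1 fit, while slide as a fixed block gave 2. Within the 5 slides the cell division median ran from −5.28 to 0.33 (4 below 0), the ovulatory cascade from 0.10 to 3.81 and immediate early genes from 0.03 to 2.65. Leukocyte markers split (−0.72 to 2.69, 3 above 0 and 2 below), and matrix proteases (0.16 to 1.98) and endothelial markers (0.12 to 1.87) did not. On 4 of 5 slides the pooled direction held for cholesterol (from −0.04), smooth muscle (−0.08 to 1.79), cytokines (−0.49 to 1.12), granulosa markers (−1.41 to 0.23) and gonadotropin and hormone receptors (−1.19 to 0.02), and on 5 for endoplasmic reticulum stress (−0.55 to −0.06). With normexp the endothelial median turned to −0.12, while relative to the median of all features the 12 called lists kept their direction under all 5 scalings.

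**Figure D1:**
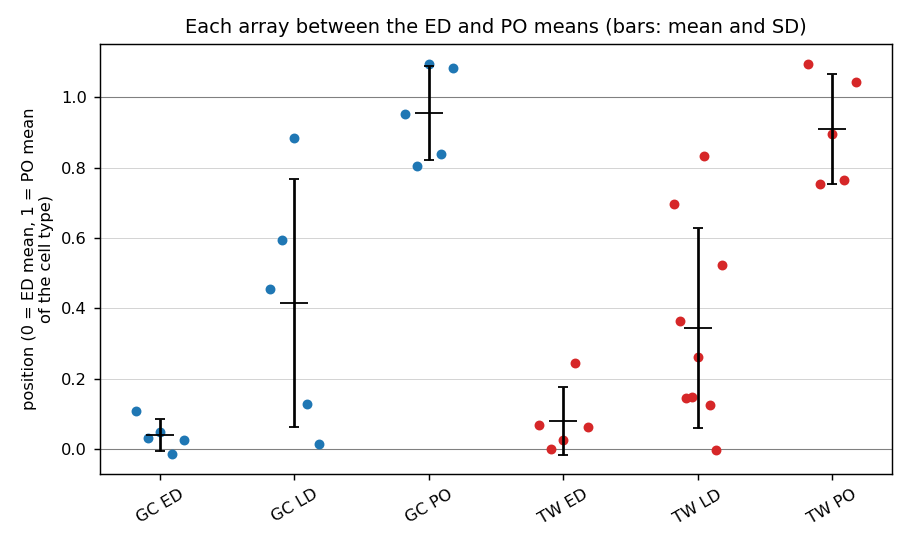
Position of each of the 34 arrays (points) between the mean ED profile (0) and the mean PO profile (1) of its cell type, no unit, for the 6 groups, with bars for mean and SD. GC LD arrays run from 0.01 to 0.88 and TW LD arrays from 0.00 to 0.83, while GC PO arrays start at 0.80 and TW PO arrays at 0.75.

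The step from LD to PO in GC asked what changes in granulosa cells before ovulation (5 and 5 arrays). PLAU, the urokinase plasminogen activator that cuts matrix, rose 68.4-fold (log2 6.10 ± 1.12 SE, adjusted p = 0.00583, 4 of 5 PO arrays beyond). PTGS2, the prostaglandin synthase, rose 15.0-fold (3.91 ± 0.89 SE, 0.0114, 4 of 5 beyond), from −0.82 ± 0.47 (SD, n = 5) to 3.09 ± 2.60 (SD, n = 5) on the array scale. SGO2, which guards cohesin at centromeres and is not in the cell division list, fell 25.8-fold (−4.69 ± 0.75 SE, 0.00548, 5 of 5 beyond). Of that list, the spindle checkpoint kinase TTK fell 21.3-fold (−4.42 ± 0.87 SE, 0.00685, 5 of 5 beyond). HSD17B1, which converts estrone to estradiol, fell 21.5-fold (−4.43 ± 1.40 SE, 0.041, 3 of 5 beyond).

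Of 24761 features, 4370 changed, 1698 higher and 2672 lower at PO. Among called features with a gene symbol the balance differed, with 711 higher and 668 lower. The lower calls include 213 unnamed probes that list 4 or more transcripts and 279 features that share 16 bases in a row with them. The other leading risers were NIM1K, a kinase (log2 6.27 ± 1.47 SE, 4 of 5 PO arrays beyond), and EDN2, an endothelin (47.3-fold, 5.56 ± 1.77 SE, 3). Next came BDNF, a neurotrophin (46.6-fold, 5.54 ± 1.01 SE, 5) and ABCC8, the sulfonylurea receptor of potassium channels (45.6-fold, 5.51 ± 0.91 SE, 5, well above background on 1 of 5 LD arrays). AGPAT4, which makes phosphatidic acid (39.9-fold, 5.32 ± 0.81 SE, 4), HSD11B1, which makes cortisol from cortisone (32.9-fold, 5.04 ± 1.26 SE, 4), and SLC2A5, a fructose transporter (30.7-fold, 4.94 ± 1.47 SE, 0), also rose. The leading fallers were HFM1, a meiotic helicase (at least 20.8-fold, −5.88 ± 1.04 SE, 5 beyond), CENPF (at least 10.8-fold, −5.15 ± 1.23 SE, 1) and NDC80 (at least 14.6-fold, −5.09 ± 1.30 SE, 0), both of the kinetochore. SPC25, also of the kinetochore (−4.53 ± 1.11 SE, 2), DLGAP5 (−4.18 ± 1.00 SE, 4), REP15 (−4.16 ± 0.72 SE, 4) and STIL, needed for centrioles (−3.82 ± 0.83 SE, 4), completed them, with adjusted p between 0.00548 and 0.0423 over all of these genes. Several were dim in one stage: at LD 4 of 5 arrays were well above background for EDN2, BDNF and AGPAT4, 3 for NIM1K and SLC2A5, and 2 for HSD11B1. At PO the number was 3 of 5 for TTK, HSD17B1, DLGAP5 and INHBB, 2 for REP15 and STIL, and 1 for SGO2 and IHH.

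Of the 8 lists camera called in this step, 5 were higher and 3 lower, and with an estimated correlation each had adjusted p = 0.508. Counts in brackets are adjusted over the list alone, higher and lower. Cell division had 0 of 61 members higher and 28 lower [0 and 47] (median −2.43, adjusted p = 3.2e-13), among them AURKB (−3.16), MKI67 (−3.72) and CCNB1 (−3.44). Glycolysis and hypoxia genes had 6 of 31 higher and 0 lower [14 and 0] (1.06, 1.4e-06), with ADM, a vasodilator peptide induced by low oxygen (10.4-fold, 3.39 ± 0.86 SE), and PDK3, which restrains pyruvate use in mitochondria (4.72-fold, 2.24 ± 0.60 SE). PGAM1 (1.92) and PFKL (1.49) of glycolysis rose too. The respiratory chain had 5 of 34 higher and 0 lower [0 and 0] (0.42, and 0.20 relative to features of the same brightness, 1.36e-05), with ATP5D (2.16-fold, 1.11 ± 0.34 SE) and NDUFA2 (1.82-fold, 0.86 ± 0.26 SE). Cholesterol synthesis and uptake had 6 of 23 higher and 0 lower [8 and 0] (0.69, 1.51e-05), with TM7SF2 (4.58-fold, 2.20 ± 0.56 SE), MVK (3.32-fold, 1.73 ± 0.44 SE) and NSDHL (1.49). Fry also called these 4 lists (adjusted p = 0.046, 0.0289, 0.0249 and 0.0249).

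Counts in brackets are adjusted over the list alone, higher and lower. Immediate early genes had 5 of 23 higher and 0 lower [6 and 1] (median 1.28, adjusted p = 0.00414), with IER3 (16.5-fold, 4.04 ± 0.94 SE) and the orphan nuclear receptor NR4A1 (5.44-fold, 2.44 ± 0.61 SE). Angiogenic factors had 5 of 22 higher and 1 lower [5 and 1] (0.63, 0.0215), with ANGPT2, which loosens vessels (11.7-fold, 3.55 ± 1.11 SE), NRP1 (2.91) and, lower, PDGFC (−2.28). Granulosa markers had 0 of 17 higher and 4 lower [0 and 4] (median −0.72, mean −1.29, 0.0212), which were HSD17B1, IHH, a hedgehog ligand (17.0-fold lower, −4.09 ± 1.06 SE), INHBB, an inhibin and activin subunit (11.5-fold lower, −3.53 ± 1.10 SE), and WT1 (−2.73). Gonadotropin receptors, inhibins and hormone receptors had 0 of 19 higher and 4 lower [0 and 4] (−0.72, 0.0302), with INHBB, TGFBR3, the inhibin coreceptor (4.35-fold lower, −2.12 ± 0.65 SE), GHR and NR3C1 (−1.68). Markers of other cell types were not called as lists. Leukocyte markers had 3 of 28 higher and 0 lower [1 and 0] (0.65, 0.0737) and smooth muscle markers 0 of 16 (0.33, 0.269). Theca markers had 0 of 16 higher and 1 lower [0 and 0] (−0.45, 0.652) and endothelial markers 0 of 13 (−0.02, 0.969).

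The remaining lists had no call in this step, with counts in brackets adjusted over the list alone, higher and lower. The ovulatory cascade had 4 of 24 higher and 2 lower [4 and 3] (median 0.66), with RGS2 (3.74) up and VCAN (−2.66) down. Cytokines had 3 of 22 higher and 0 lower [4 and 1] (1.03), matrix proteases 2 of 25 and 0 [2 and 0] (0.38), and prostaglandin genes 2 of 16 and 0 [3 and 0] (0.38, PTGS1 2.67). Antioxidant genes had 3 of 25 and 1 [4 and 2] (0.29) and apoptosis regulators 3 of 28 and 3 [3 and 3] (0.18, BCL2L1 2.55 and BCL2 −1.92). Steroid synthesis had 3 of 21 and 2 [3 and 2] (0.34, TSPO 1.73), and collagens 2 of 25 and 1 [2 and 0] (0.16). Cell junctions had 1 of 20 and 3 [1 and 3] (−0.18, CLDN4 3.06 and OCLN −3.42) and endoplasmic reticulum stress 0 of 23 (0.19). Cell cycle inhibitors had 0 of 17 higher and 2 lower (CCND2 −1.25 and CCND3 −1.38) [0 and 0] with a median of 0.07, a mean of −0.15 and a test pointing lower. The insulin-like growth factor system had 1 of 15 and 1 [1 and 1] with a median of 0.06, a mean of 0.12 and a test pointing lower. The 4 oocyte (−0.03) and 4 red blood cell genes (0.12) were not tested. Steroid and receptor genes named in advance were not called: STAR 1.34 ± 1.06 SE (adjusted p = 0.394), CYP11A1 1.27 ± 0.67 SE (0.19), CYP17A1 −0.31 ± 0.87 SE (0.84) and CYP19A1 0.06 ± 0.65 SE (0.961). All 9 other CYP19A1 probes kept went the opposite way (−1.28 to −0.84), so the value of the chosen probe does not show that CYP19A1 stayed level. Values for the others were FSHR −0.72 ± 1.15 SE (0.699), LHCGR −0.29 ± 0.69 SE (0.808), INHA −0.07 ± 0.24 SE (0.863), INHBA −0.76 ± 0.32 SE (0.11) and VEGFA 0.80 ± 0.59 SE (0.358).

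GC LD 3 and GC PO 2 stood apart in this step. GC LD 3 lay at 0.88 between the ED and PO means. PTGS2 was at −1.55 on GC PO 2 against 3.92 to 4.42 on the other 4 PO arrays. The count was 7284 without GC LD 3, 2114 without GC LD 4, 2326 without GC LD 5, 2339 without GC PO 3 and 2329 without GC PO 5. It was 7440 without both GC LD 3 and GC PO 2, a pair chosen after seeing the data. Median centring moved the median of all features by 0.11 and the share of higher calls from 38.9% to 49.5%. Relative to that median the 8 called lists kept their direction under all 5 scalings. With slide as a fixed block 4400 features were called, but not ANGPT2 (adjusted p = 0.0735), NDUFA2 (0.0586) and HSD17B1 (0.0548). Within the 5 slides the medians ran from −4.68 to 0.41 for cell division (4 below 0), −0.28 to 1.93 for glycolysis, 0.12 to 0.69 for the respiratory chain, 0.35 to 1.51 for cholesterol and −1.70 to −0.07 for granulosa markers. Within-slide medians ran from −0.59 to 2.83 for immediate early genes, 0.35 to 2.02 for angiogenic factors and −1.84 to −0.10 for gonadotropin and hormone receptors, and PTGS2 ran from −1.31 to 5.68 (4 above 0).

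**Figure D2:**
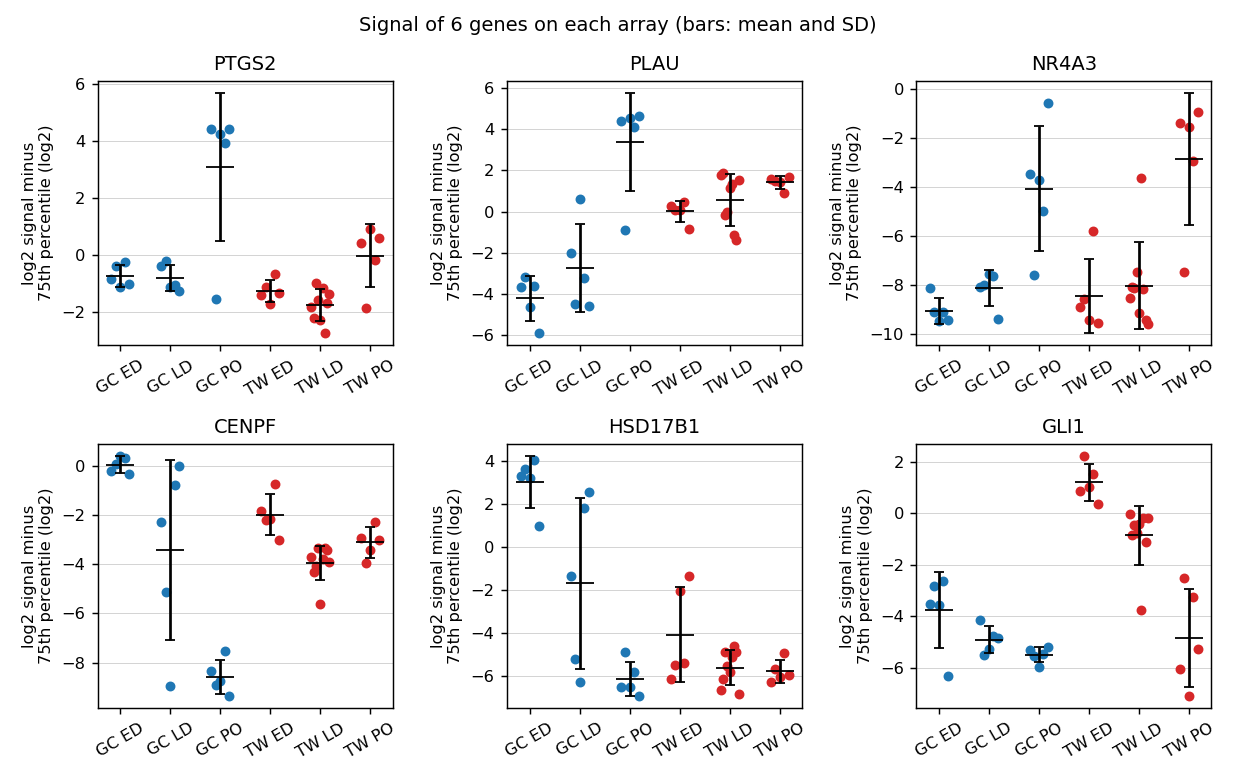
Signal of PTGS2, PLAU, NR4A3, CENPF, HSD17B1 and GLI1 (log2 minus the array's 75th percentile) on each array (points) of the 6 groups, with bars for mean and SD. PTGS2 is at 3.92 to 4.42 on 4 of 5 GC PO arrays and at −1.55 on the fifth, and GLI1, 15.8-fold lower at PO than at LD in TW, is lower on 3 of 5 TW PO arrays than on all TW LD arrays.

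The step from ED to LD in TW asked the same of the theca wall (9 LD and 5 ED arrays). CCND2, the gene of cyclin D2, which drives entry into the cell cycle, fell 1.87-fold (log2 −0.90 ± 0.13 SE, adjusted p = 0.026, 9 of 9 LD arrays beyond). STMN1, which takes microtubules apart, fell 2.11-fold (−1.08 ± 0.15 SE, 0.026, 8 of 9 beyond), and the histone gene H2BC21 rose 3.14-fold (1.65 ± 0.25 SE, 0.0306, 9 of 9 beyond). Cell division genes were lower as a list, with a median of −0.91 over 61 genes and 0 called (camera adjusted p = 1.4e-31, and adjusted p = 0.508 with an estimated correlation). Adjusted over the list alone, 44 were lower, and MCM6 was at −0.91 ± 0.17 SE (adjusted p = 0.066, 9 of 9 beyond). Cholesterol genes were higher as a list (median 0.66 over 23, adjusted p = 8.1e-11, and adjusted p = 0.508 with an estimated correlation), with 0 called and 12 higher adjusted over the list alone. Fry called cell division (0.0131), cholesterol (0.029) and apoptosis regulators (0.0249).

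Of 26940 features 10 changed, 4 higher and 6 lower. Besides the 3 genes above, a probe described as KIF15, a spindle motor, fell 3.47-fold (log2 −1.80 ± 0.31 SE, adjusted p = 0.0418), and a probe described as a killer cell lectin-like receptor rose by 1.13, both named after their values were seen. The other 5 had no gene name (1.75, 1.55, −2.46, −0.69 and −0.82). The 10 genes named in advance were not called: CYP11A1 0.30 ± 0.28 SE (adjusted p = 0.659), CYP17A1 0.01 ± 0.17 SE (0.984) and CYP19A1 0.56 ± 0.99 SE (0.835). CYP17A1 was saturated on 8 of 9 LD and 5 of 5 ED arrays, so its value does not show that it stayed level. Receptors and STAR were at FSHR −0.65 ± 0.79 SE (0.749, well above background on 3 of 9 LD and 2 of 5 ED arrays), LHCGR −0.62 ± 0.67 SE (0.709), and STAR 0.15 ± 0.32 SE (0.862). The rest were INHA 0.37 ± 0.39 SE (0.707), INHBA −0.69 ± 0.53 SE (0.571), PTGS2 −0.51 ± 0.38 SE (0.551, other probes −0.35 to 1.17) and VEGFA 0.03 ± 0.17 SE (0.947). Camera called 11 of the 25 lists tested, 10 higher and 1 lower, each with 0 members called. None was called with an estimated correlation (adjusted p = 0.508 except where given). Counts in brackets are adjusted over the list alone, higher and lower. The higher lists besides cholesterol were cytokines (median 0.54 over 33 genes, adjusted p = 8.6e-05 [2 and 0]), leukocyte markers (0.53 over 31, 0.000239 [0 and 0]), immediate early genes (0.45 over 24, 0.00231 [0 and 0]) and matrix proteases (0.69 over 25, 0.0033 [1 and 0]). Camera also called the respiratory chain (0.17 over 34, and 0.11 relative to features of the same brightness, 0.00414, adjusted p = 0.585 with an estimated correlation [0 and 0]), antioxidant genes (0.19 over 25, 0.00502 [0 and 0]) and the ovulatory cascade (0.44 over 26, 0.0134 [0 and 0]). The last were endoplasmic reticulum stress (0.22 over 24, 0.0161, adjusted p = 0.565 with an estimated correlation [0 and 0]) and apoptosis regulators (0.16 over 29, 0.0193 [0 and 0]).

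Lists not called in this step were insulin-like growth factors (median 0.35), prostaglandins (0.38), steroid synthesis (0.15), glycolysis (0.08), endothelial markers (−0.20), collagens (−0.03), angiogenic factors (0.06) and cell cycle inhibitors (0.26, with CCND2 called). Adjusted over the list alone, 3 of 16 theca markers were lower (median 0.00, mean −0.23), CCND2 was lower, 1 gene each of the prostaglandin, steroid synthesis and granulosa lists was higher, and no other member of an uncalled list passed. Median and mean differed in sign for gonadotropin and hormone receptors (0.02 and −0.20, tested as lower), cell junctions (−0.02 and 0.01, tested as lower), granulosa markers (−0.02 and 0.07, tested as lower) and oocyte genes (0.17 and −0.01, tested as lower). Smooth muscle markers (−0.02 and −0.01) tested as higher, and red blood cell genes were at 0.60, untested. The calls of this step were few and moved with most settings. Leaving out 1 array gave 0 to 31, with 0 without TW ED 1, 2, 3 or 4, TW LD 4 or 9 or TW PO 3. It gave 2 without TW LD 1 or 2, 3 without TW PO 1 or 5, 4 without TW LD 6, 5 without TW PO 4, 16 without TW LD 3, 17 without TW LD 8 and 31 without TW ED 5. Using slide as a fixed block gave 0 (with adjusted p from 0.0691 to 0.071 for the 3 named genes) and array weights gave 481. Relative to the median of all features, which normexp moved by 0.19, the respiratory chain (−0.10 to 0.15), endoplasmic reticulum stress (−0.01 to 0.20) and antioxidant genes (−0.01 to 0.18) were each below 0 under 1 of 5 scalings. The share of higher calls, 40.0% here, was 22.9%, 16.2% and 14.5% with quantile normalization, median centring and the deposited values. Within the 5 slides the medians ran from −1.41 to −0.41 for cell division, −0.49 to 1.27 for cholesterol (4 above 0) and 0.24 to 1.19 for cytokines. The respiratory chain (−0.28 to 0.24) and antioxidant genes (−0.37 to 0.36) split, with 3 above 0 and 2 below. The ovulatory cascade ran from 0.16 to 0.98, and 4 of 5 slides were above 0 for leukocyte markers (−0.06 to 0.86), immediate early genes (−0.09 to 0.83), matrix proteases (−0.03 to 1.51), endoplasmic reticulum stress (−0.04 to 0.44) and apoptosis regulators (−0.04 to 0.38).

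The step from LD to PO in TW asked what changes in the theca wall before ovulation (5 PO and 9 LD arrays). SST, the gene of somatostatin, rose 74.9-fold (log2 6.23 ± 0.88 SE, adjusted p = 0.00471, 5 of 5 PO arrays beyond), well above background on 5 of 5 PO and 3 of 9 LD arrays. PENK, the precursor of enkephalins, rose 45.0-fold (5.49 ± 1.13 SE, 0.00769, 4 of 5 beyond), and the orphan nuclear receptor NR4A3 rose 35.8-fold (5.16 ± 1.03 SE, 0.00731, 4 of 5 beyond), with 4 of 5 PO and 1 of 9 LD arrays well above background. Leukocyte markers rose as a list, with 22 of 31 called higher and 0 lower (median 1.35, camera adjusted p = 1.3e-12, and adjusted p = 0.508 with an estimated correlation). GLI1, the transcription factor that reports hedgehog signals, fell 15.8-fold (−3.99 ± 0.68 SE, 0.00471, 3 of 5 beyond).

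Of 26899 features, 4153 changed, 2310 higher and 1843 lower at PO. Other leading risers were CGA, the alpha subunit of glycoprotein hormones (42.8-fold, log2 5.42 ± 1.34 SE, 0 of 5 PO arrays beyond) and FGF7, a fibroblast growth factor (28.1-fold, 4.81 ± 1.29 SE, 0). They also included TBX19 (25.7-fold, 4.69 ± 1.45 SE, 2), MEDAG (24.5-fold, 4.61 ± 0.95 SE, 2) and the acute-phase serum amyloid A genes. SAA (25.0-fold, 4.64 ± 0.89 SE, 4) and SAA1 (22.9-fold, 4.52 ± 0.73 SE, 4) are close copies, and whether their probes tell them apart was not tested. Other leading fallers were NR0B2, a nuclear receptor that represses others (7.95-fold, −2.99 ± 0.78 SE, 3), FTCD (7.14-fold, −2.84 ± 0.81 SE, 1), MLPH (6.97-fold, −2.80 ± 0.64 SE, 3) and TNNI1, a troponin (5.17-fold, −2.37 ± 0.74 SE, 0). KCTD14 (5.02-fold, −2.33 ± 0.44 SE, 4), PON1 (4.60-fold, −2.20 ± 0.53 SE, 3) and CRIPTO (4.43-fold, −2.15 ± 0.49 SE, 4) fell too, and adjusted p lay between 0.00471 and 0.0385 over all of these genes. Some risers named here and below were dim at LD, with 8 of 9 arrays well above background for SAA1, 7 for EREG, 6 for TBX19, 5 for CXCL6, 4 for FGF7 and MMP1, 3 for SAA, AREG and ESAM, and 2 for MEDAG and FOXM1.

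Camera called 12 of the 25 lists in this step, 9 higher and 3 lower, with adjusted p = 0.508 with an estimated correlation except where given. Counts in brackets are adjusted over the list alone, higher and lower. Leukocyte markers [27 and 1] included the T-cell adhesion molecule CD2 (4.11-fold, log2 2.04 ± 0.39 SE), the chemokine receptor CXCR4 (4.44-fold, 2.15 ± 0.60 SE), CD68 (1.55) and CD163 (1.66) of macrophages. The ovulatory cascade had 14 of 26 higher and 0 lower [17 and 0] (median 1.47, adjusted p = 2e-06), with the EGF-like factors EREG (19.9-fold, 4.31 ± 1.17 SE) and AREG (13.4-fold, 3.74 ± 0.90 SE), PTGS2 (3.35-fold, 1.75 ± 0.38 SE, 4 of 5 beyond) and the progesterone receptor gene PGR (1.16). Immediate early genes had 13 of 24 higher and 1 lower [16 and 1] (1.25, 3e-07), with NR4A3, NR4A2 (19.4-fold, 4.28 ± 0.87 SE), ATF3 (2.49) and, lower, HMOX1 (−1.05). Cytokines, chemokines and adhesion genes had 13 of 33 higher and 1 lower [15 and 1] (1.02, 1.5e-05), with IL1RN, the interleukin-1 antagonist (9.21-fold, 3.20 ± 1.05 SE), CXCL6 (8.35-fold, 3.06 ± 0.75 SE), SELP (2.34) and, lower, CXCL10 (−1.18). Matrix proteases had 8 of 25 higher and 0 lower [13 and 0] (0.89, 0.000239), with the collagenase MMP1 (13.8-fold, 3.79 ± 1.16 SE) and ADAMTS4 (9.69-fold, 3.28 ± 0.71 SE). On the PO arrays as a whole, leukocyte markers lay 0.56 to 1.92 above their mean over TW arrays. Whether the other lists follow the leukocyte markers array by array was not tested.

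Camera also called vessel, matrix and cell division lists higher, none of them with an estimated correlation, and counts in brackets are adjusted over the list alone, higher and lower. Endothelial markers had 9 of 23 higher and 0 lower [12 and 0] (median 0.90, adjusted p = 1.5e-05), with ESAM (3.08-fold, log2 1.62 ± 0.47 SE), CDH5 (2.48-fold, 1.31 ± 0.33 SE) and PECAM1 (1.25). Angiogenic factors had 10 of 26 higher and 0 lower [13 and 1] (0.70, 0.000597, and −0.0083 as the median with normexp), with EDN2 (7.64-fold, 2.93 ± 0.73 SE), FGF7 and FGF2 (2.60). Collagens and structural matrix had 6 of 30 higher and 0 lower [8 and 1] (0.49, 0.0068, not called by fry), with COL14A1 (4.70-fold, 2.23 ± 0.61 SE) and FBLN1 (2.19-fold, 1.13 ± 0.36 SE). Cell division genes had 7 of 61 higher and 0 lower [18 and 0] (0.68, 2.8e-06, adjusted p = 0.565 with an estimated correlation, not called by fry), with FOXM1 (2.41-fold, 1.27 ± 0.40 SE) and MKI67 (2.37-fold, 1.24 ± 0.35 SE), both marks of cycling cells. The rise did not take the list above ED. In TW PO minus ED, compared after the values were seen, 0 of 61 were higher and 8 lower (median −0.27).

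The lower lists follow, with counts in brackets adjusted over the list alone, higher and lower. The respiratory chain had 0 of 34 higher and 14 lower [1 and 23] (median −0.45, adjusted p = 2.15e-09), with NDUFS3 of complex I (1.75-fold, log2 −0.81 ± 0.14 SE, 5 of 5 beyond) and SDHA of complex II (1.68-fold, −0.74 ± 0.20 SE). Cholesterol synthesis and uptake had 1 of 23 higher and 4 lower [1 and 4] (−0.50, 0.00455, adjusted p = 0.565 with an estimated correlation), with MVD (1.95-fold, −0.96 ± 0.21 SE) and FDFT1, the squalene synthase (1.89-fold, −0.92 ± 0.20 SE), lower. Antioxidant genes had 3 of 25 higher and 8 lower [3 and 10] (−0.35, 0.018, adjusted p = 0.544 with an estimated correlation), with GSR (−1.10) and PRDX5 (−0.70) lower and GSTA1 (5.64-fold, 2.50 ± 0.77 SE) and GPX3 (3.00-fold, 1.58 ± 0.42 SE) higher. Fry called 8 of these 12 lists, not collagens (adjusted p = 0.0624), cell division (0.0925), antioxidant genes (0.0925) or cholesterol (0.157), and it also called apoptosis regulators (0.0198) and cell cycle inhibitors (0.0131).

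Further lists passed no camera threshold in this step, and brackets hold counts adjusted over the list alone, higher and lower. Steroid synthesis had 1 of 21 higher and 5 lower [3 and 5] (median −0.50), with CYP11A1, which starts steroid synthesis (1.81-fold lower, log2 −0.86 ± 0.28 SE, adjusted p = 0.0463), NR5A1 (−1.41) and FDXR (−1.38). Theca markers had 1 of 16 higher and 3 lower [2 and 3] (−0.24), which were THBS2 (1.05) and, lower, GLI1, PTCH1 (−1.59) and HHIP (−1.86). Cell cycle inhibitors had 3 of 17 and 1 [6 and 3] (0.53, CDKN1A 1.43), and apoptosis regulators 6 of 29 and 2 [8 and 2] (0.29, BIRC3 1.96). The insulin-like growth factor system had 4 of 16 and 0 [4 and 0] (0.10, IGFBP3 2.59) and prostaglandin genes 4 of 17 and 0 [4 and 3] (0.58, PTGIS 1.76). Glycolysis had 4 of 31 and 4 [4 and 4] (0.05), with PFKFB3 (2.02) higher and ALDOC (−1.03) lower. Cell junctions had 4 of 21 and 0 [4 and 0] (0.28), smooth muscle markers 2 of 18 and 0 [2 and 0] (0.28, MCAM 1.64) and endoplasmic reticulum stress 2 of 24 and 1 [2 and 1] (0.16). Gonadotropin and hormone receptors had 1 of 19 and 1 [1 and 1] (−0.32). Granulosa markers had 1 of 17 and 1 [2 and 1] with a median of −0.15, a mean of 0.03 and a test pointing lower. Oocyte genes had 0 of 5 (−0.21) and red blood cell genes, untested as a list, 1 of 4 and 0 [2 and 0] (1.24, HBA2 1.40). Genes named in advance and not called were CYP17A1 (−0.25 ± 0.17 SE, adjusted p = 0.321, saturated on 4 of 5 PO and 8 of 9 LD arrays), STAR (−0.50 ± 0.30 SE, 0.251) and LHCGR (−1.11 ± 0.67 SE, 0.258). Also uncalled were CYP19A1 (−0.94 ± 0.99 SE, 0.535), FSHR (−0.37 ± 0.79 SE, 0.779, well above background on 1 of 5 PO and 3 of 9 LD arrays, another probe at 0.12), INHA (−0.38 ± 0.39 SE, 0.523), INHBA (0.09 ± 0.53 SE, 0.919) and VEGFA (0.25 ± 0.17 SE, 0.319, other probes −0.11 to 0.37).

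Scaling set the balance of this step. The share of higher calls was 55.6% here, 39.9% with quantile normalization, 26.2% with median centring, 39.4% with normexp and 43.0% in the deposited values. The first 3 of these alternatives moved the median of all features by −0.11, −0.21 and −0.26. Relative to that median all 12 called lists kept their direction, with leukocyte markers between 1.32 and 1.45, and the ovulatory cascade between 1.07 and 1.44. The respiratory chain stayed between −0.48 and −0.17, cholesterol between −0.52 and −0.21 and antioxidant genes between −0.38 and −0.15, while theca markers (−0.26 to 0.12) did not. Unadjusted for that median, normexp turned ESAM (−0.22) and FOXM1 (−0.34). Relative to features of the same brightness the respiratory chain was at −0.24, cholesterol at −0.35 and antioxidant genes at −0.13. With slide as a fixed block 1756 features were called, and 19 of the 41 called named genes were not, with adjusted p from 0.0554 (CGA) to 0.157 (FBLN1). These 19 also included FGF7, TBX19, MMP1, IL1RN, CXCL6, EDN2, GSTA1, COL14A1, ESAM, CDH5, FOXM1, MKI67, NR0B2, FTCD, TNNI1, CYP11A1 and SDHA. The count was 2102 without TW PO 1, 2358 without TW PO 3 and 1331 without TW PO 5. It was 1887 with only the TW LD arrays on full slides and 1087 with 1 TW LD value per slide. Within the 5 slides the medians ran from 1.12 to 1.52 for leukocyte markers, 0.81 to 1.82 for the ovulatory cascade, and 0.71 to 1.65 for immediate early genes. They ran from 0.61 to 0.84 for cytokines, 0.05 to 1.46 for matrix proteases, 0.09 to 0.79 for cell division and −0.66 to −0.18 for the respiratory chain. In 4 of 5 slides the pooled direction held for endothelial markers (−0.00 to 1.19), angiogenic factors (−0.20 to 1.07), collagens (−0.50 to 0.57), cholesterol (−0.84 to 0.83) and antioxidant genes (−0.54 to 0.29).

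**Figure D3:**
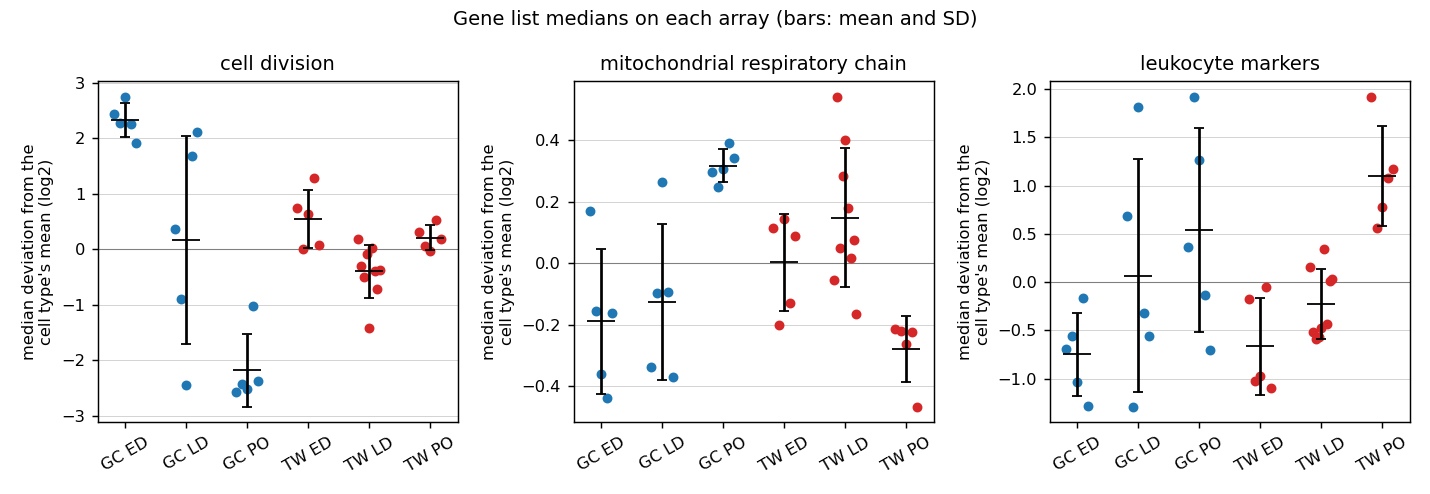
Median deviation of the measured genes of 3 lists from their mean in the cell type (log2) on each array (points) of the 6 groups, with bars for mean and SD. Cell division lies at 1.92 to 2.75 on GC ED arrays and at −2.58 to −1.03 on GC PO arrays, and leukocyte markers lie at 0.56 to 1.92 on TW PO arrays.

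Whether the 2 layers changed differently was tested with an interaction, the GC change minus the TW change. From LD to PO, AGPAT4 (log2 5.77 ± 0.82 SE, adjusted p = 0.000324), NR0B2 (5.54 ± 1.16 SE, 0.0021), GNAZ (5.31 ± 0.91 SE, 0.000604) and PLAU (5.24 ± 1.18 SE, 0.00325) moved higher in GC than in TW. CENPF (−5.98 ± 1.22 SE, 0.00175), NDC80 (−5.98 ± 1.25 SE, 0.00213), SST (−5.78 ± 1.23 SE, 0.00234) and E2F8, which acts late in the cell cycle (−5.33 ± 0.98 SE, 0.000882), moved lower in GC than in TW. These sizes are not exact: CENPF, NDC80 and E2F8 were not well above background on any GC PO array, while SST was on 1 of 5 GC PO and 1 of 5 GC LD arrays and GNAZ on 2 of 5 GC LD arrays. Cell division genes moved lower in GC for 44 of 61 members and higher for 0 (median −3.22), and adjusted over the list alone 51 were lower. Respiratory chain genes moved higher in GC for 23 of 34 members and lower for 0 (median 0.85, and 0.49 relative to features of the same brightness), and adjusted over the list alone 28 were higher.

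Of 27682 features, 5439 changed differently from LD to PO, 2427 with a positive interaction (the GC change was the higher one) and 3012 with a negative one. Among those with a gene symbol the balance was the other way, with 1030 positive and 869 negative. Counts in brackets are adjusted over the list alone, positive and negative. Cholesterol genes were positive for 10 of 23 and negative for 0 [13 and 0] (median 1.20), among them NSDHL (2.30 ± 0.40 SE) and FDFT1 (1.46), and glycolysis genes for 11 of 31 and 0 [14 and 1] (0.96), among them BNIP3 (2.31) and GPI (1.66). Steroid synthesis had 5 of 21 positive and 2 negative [5 and 2] (0.81), with CYP11A1 at 2.13 ± 0.69 SE (adjusted p = 0.028), TSPO at 2.47 and HSD17B4 at 2.49, and antioxidant genes had 5 of 25 and 1 [6 and 1] (0.60, and 0.25 relative to features of the same brightness). Theca markers had 3 of 16 and 1 [3 and 1], with the hedgehog targets GLI1 (3.40), HHIP (3.20) and PTCH1 (2.38) on the positive side, with a list median of −0.12 and mean of 0.17. No list test of the interaction was run. Lists with a negative median included granulosa markers (0 and 4 of 17 [0 and 5], −1.18), endothelial markers (0 and 2 of 23 [0 and 2], −1.26), and collagens (0 and 4 of 30 [0 and 3], −0.48). They also included cytokines (1 and 4 of 34 [1 and 4], −0.75, IL6 −3.54), and leukocyte markers (0 and 3 of 31 [0 and 1], −0.71). The ovulatory cascade (0 and 3 of 26 [0 and 2], −0.52) and angiogenic factors (1 and 4 of 27 [1 and 4], −0.14, relative to the median of all features −0.04 to 0.08 over the 5 scalings, and 0.14 relative to features of the same brightness) had negative medians as well. The remaining lists were apoptosis regulators (4 and 4 of 29, −0.14), cell cycle inhibitors (0 and 2 of 17 [0 and 1], −0.50), cell junctions (2 and 3 of 21, −0.37) and immediate early genes (1 and 1 of 25, −0.09, NR4A2 −4.39). There followed matrix proteases (1 and 1 of 25, −0.23), prostaglandin genes (2 and 0 of 17, −0.15, and 0.07 relative to features of the same brightness), endoplasmic reticulum stress (1 and 0 of 24, −0.05) and insulin-like growth factors (0 and 1 of 16, −0.29). The last were smooth muscle markers (0 and 1 of 18 [0 and 0], 0.24), oocyte genes (0 and 1 of 6, −0.23, and 0.17 relative to features of the same brightness), gonadotropin and hormone receptors (0 and 0 of 20, −0.86) and red blood cell genes (0 and 0 of 4, −1.03). Counts adjusted over the list alone were the same where no bracket is printed.

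Median centring and normexp moved the share of positive interactions from 44.6% to 69.0% and 58.0%, and moved the median of all features by 0.32 and 0.35 (quantile normalization 0.13, deposited values 0.12). Relative to that median, cell division stayed between −3.12 and −1.97, cholesterol between 0.82 and 1.30, glycolysis between 0.49 and 1.07 and the respiratory chain between 0.49 and 0.96. With slide as a fixed block the count was 4766. From ED to LD, 0 of 27721 features had a limma interaction call, with 2126 at an unadjusted p under 0.05. Other settings gave 4 (deposited values), 1 (mean of a gene's probes), 1 (random slide block), 2 (fixed slide block), 1 (array weights) and 1 (without slide 7). Leaving out an array gave 270 without GC LD 5, 9 without GC LD 4 and 1 without TW LD 1. Adjusted over the list alone, collagens had 2 positive genes, cytokines 1 and theca markers 1, and endoplasmic reticulum stress 1 negative gene.

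**Figure D4:**
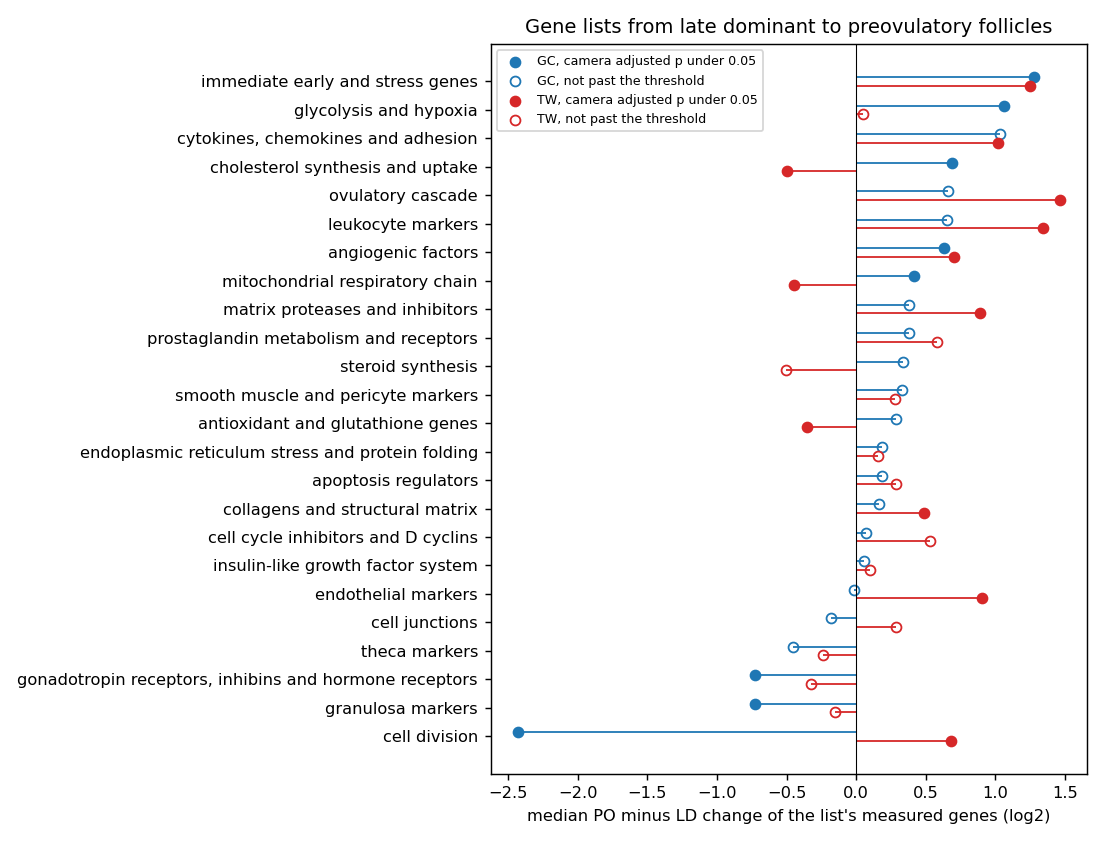
Median PO minus LD change (log2) of the measured genes of each of 24 lists in GC (blue) and TW (red), filled where the camera adjusted p was under 0.05, none of which held with an estimated correlation. Cell division is at −2.43 in GC and 0.68 in TW, and the respiratory chain at 0.42 and −0.45.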

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

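The tests of an exchange of arrays, of theca cells, of scaling, of cell shares and of brightness, and the splits for the 2 interactions, were chosen after the result was seen, while the other splits of the arrays and the test of a repeated sequence were set before.

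Among GC arrays, GC LD 3 lay closest to GC PO 2 (r = 0.987 across features, which are not independent replicates), with cell division medians of −2.45 and −2.42 and leukocyte marker medians of 1.81 and 1.92. The median of −2.42 on GC PO 2 lies below the other 4 GC LD arrays (−0.90 to 2.12, SD 1.36) by more than their SD. That was the outcome set for no exchange. GC LD 3 lies as low, so with either labelling 1 LD array lies there, and the test does not decide whether the 2 arrays were exchanged. The exchange would leave these 2 arrays in different stages, so by itself it would not account for their likeness. Theca cells in GC LD 3 are argued against by theca markers at −0.44, where another GC LD array stood at 1.74. An exchange, a wrong label of GC LD 3 alone or of GC PO 2 alone, and cells of the leukocyte kind in both samples stay open. So do follicles of GC LD 3 and GC PO 2 in like states, a biological explanation that the design names as stage, which was not tested. PLAU was at −0.88 on GC PO 2 and 0.59 on GC LD 3. It was at 4.13 to 4.66 on the other 4 GC PO arrays and −4.58 to −1.98 on the other 4 GC LD arrays. PTGS2 was at −1.55 on GC PO 2 and −1.15 on GC LD 3, against 3.92 to 4.42 on the other 4 GC PO arrays and −1.27 to −0.23 on the other 4 GC LD arrays.

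Of 61 cell division genes, 28 fell in GC from LD to PO, while 0 fell and 7 rose in TW, with a median interaction of −3.22. Over both steps in TW, PO minus ED, 0 of the 61 were higher and 8 lower (median −0.27). Scaling between arrays is argued against, since over the other 4 scalings the median interaction nearest to 0 was −1.73. A lower share of the theca's own cells, as the only change of cells at PO, was set to raise leukocyte and smooth muscle markers alike. The leukocyte median exceeded the smooth muscle median by 0.96 more in TW PO than in TW LD (exact permutation p = 0.00500, two-sided, 5 and 9 arrays, 2002 assignments). That was the outcome set against such a lower share. It does not decide, as ACTA2 is in both the theca and the smooth muscle lists. Smooth muscle cells may themselves count among the theca's own cells. A lower share, alone or together with an entry of leukocytes, stays open. So does a rise in dividing cells of a type that entered the theca wall. A difference between the layers themselves, which may be biological, also stays open and is put forward only as a hypothesis.

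A group of 283 probes without a gene name, each listing 4 or more transcripts, was lower in GC at PO for 213 of 256 tested features and higher for 1 (median −1.90), and in TW lower for 2 and higher for 2 of 260 (median −0.22). Signal from a sequence repeated in many transcripts had its values present: features outside the group that share 16 bases in a row with it had a median of −1.88 (382 features, 279 lower, 4 higher), under the bound of −1 set beforehand. A bend of the scale at bright spots is argued against by a median of 0.12 (quartiles −0.39 and 0.57) over 7454 other features between the quartiles of the group's brightness (median level 0.67 against 1.18). The data are consistent with a repeated sequence as the source, which sequence it is was not determined, and no biological explanation was tested.

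Other splits of the arrays gave as many calls as the real one in the following numbers out of 100, the real split included. For GC PO minus LD the number was 2, with 4650 calls at most elsewhere against 4370, in the split that exchanges GC PO 2 and GC LD 3. For TW PO minus LD it was 1 (highest other 1491 against 4153), for GC minus TW 1 (5253 against 14471), for TW LD minus ED 2 (98 against 10), for the interaction from LD to PO 1 (2479 against 5439) and for the list tests 2 (45 against 43, median of the others 26). All 6 lay under the bound of 5 in 100. Chance is thereby argued against for the counts as a whole in GC PO minus LD, TW PO minus LD, GC minus TW and the interaction from LD to PO. In GC minus TW the splits cannot tell cell type from slide, as only slides 2 and 8 hold both layers. Chance is not excluded for TW LD minus ED, where another split gave 98 calls. Slide as a fixed block, which the splits left aside, gave 0 calls there. Nor is it excluded for single list calls, as reassigned stages gave a median of 26 of them at the preset correlation. For GC LD minus ED the number was 13 (35 against 1), so chance cannot be excluded. For the interaction from ED to LD it was 100, as the real count was 0, and the highest other was 20. For the interactions, stages were reassigned within each cell type after the stage change common to both was taken out. Draws that reassigned the cell type within each stage carry the GC minus TW difference into the interaction, so nothing is drawn from them. They gave 2 of 100 from LD to PO (8851 at most elsewhere against 5439) and 100 from ED to LD (5474 against 0). The highest counts of 35 and 98 were several times the real 1 and 10, while the median of the other splits was 0 in both comparisons. More calls than the real split came from 10 splits for GC LD minus ED and from 1 for TW LD minus ED. Whether a structure of the samples beyond the groups lies behind these counts was not tested.

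In 37 of 300 groups of values, 1 array stood apart, by a gap to its neighbour that took an unusual share of the group's range (given in parentheses). Chance would give about 1 in 20. GC PO 2 was low for PTGS2 (0.915), PLAU (0.903), NIM1K (0.879), AGPAT4 (0.837) and FSHR (0.719) and high for CYP11A1 (0.772). GC LD 3 was high for MVK (0.858) and AGPAT4 (0.752), and GC LD 2 for ANGPT2 (0.827). GC PO 4 was low for STAR (0.817) and high for the cell division list (0.872), and GC PO 5 was low for STIL (0.787). GC ED 5 was low for VEGFA (0.739) and the matrix protease list (0.718), and GC ED 1 for the percentage of spots well above background (0.726). TW LD 6 was high for NR4A2 (0.711), NR4A3 (0.646), AREG (0.559) and the cytokine list (0.505), and low for GLI1 (0.708) and KCTD14 (0.497). TW LD 1 was low for FDFT1 (0.605) and the cholesterol list (0.544). TW ED 4 was high for STMN1 (0.752), its position between the ED and PO means (0.726) and its variation of repeated probes (0.903), and low for the cholesterol list (0.798). TW PO 2 was low for ADAMTS4 (0.887) and high for NDUFS3 (0.807). TW PO 4 was low for FGF7 (0.884) and CGA (0.768) and high for LHCGR (0.746) and the variation of repeated probes (0.90). TW PO 5 was low for FSHR (0.789), FDFT1 (0.745) and the respiratory chain list (0.806) and high for ESAM (0.742).

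The change from LD to PO differed between the layers by the interaction test for 5439 features, among them AGPAT4 (5.77), NR0B2 (5.54), GNAZ (5.31) and PLAU (5.24), and, with the lower change in GC, CENPF (−5.98), NDC80 (−5.98), SST (−5.78) and E2F8 (−5.33), sizes that are not exact where GC arrays were dim.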

How the results depend on the processing

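The settings without slide 7, without both GC LD 3 and GC PO 2, and with median centring for the list tests were chosen after seeing the data. Of 5812 values of named genes under other settings and with single arrays left out, 5392 kept their direction and their side of the threshold, 390 lost a call, 28 gained one and 2 turned. Of 4310 list medians, 4123 kept both, 132 lost a call, 52 gained one and 3 turned. All 5 that turned did so with normexp: ESAM (−0.22) and FOXM1 (−0.34) in TW PO minus LD, the endothelial markers in GC LD minus ED (−0.12), the theca markers in TW LD minus ED (−0.028) and the angiogenic factors in TW PO minus LD (−0.0083). The cause was not tested here or below except where the construction gives it.

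Counts that moved by over 1.5 times follow by setting. With normexp they were 0 for GC LD minus ED, 2846 for GC PO minus LD, 0 for TW LD minus ED, 1413 for TW PO minus LD, 2791 for the interaction from LD to PO and 9562 for GC minus TW. Array weights gave 9013 for GC PO minus LD, 481 for TW LD minus ED, 9299 for TW PO minus LD, 8888 for the interaction from LD to PO and 1 for that from ED to LD. For TW LD minus ED, quantile normalization gave 35, median centring 37, the deposited values 76, no filter 3 and slide as a random block 28. Median centring gave 6335 for TW PO minus LD. The deposited values gave 0 for GC LD minus ED and 4 for the interaction from ED to LD, and the mean of a gene's probes and a random slide block gave 1 each for the latter. With slide as a fixed block the counts were 2 for GC LD minus ED, 0 for TW LD minus ED, 1756 (1131 higher, 625 lower) for TW PO minus LD and 2 for the interaction from ED to LD. A further threshold of 2-fold, which can only remove calls, left 2189 (1699 higher, 490 lower) for TW PO minus LD and 6924 (1825 higher, 5099 lower) for GC minus TW.

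Other sets of arrays also mattered. All 34 arrays in 1 fit gave 1606 for GC LD minus ED, 7808 for GC PO minus LD, 0 for TW LD minus ED and 2006 for TW PO minus LD. Only the arrays of the stages compared, fewer than in the fit used, gave 0, 1469, 0 and 2686 in the same order. TW LD arrays on full slides gave 5 for TW LD minus ED and 1887 for TW PO minus LD, and 1 TW LD value per slide gave 3 and 1087. Without slide 7, 3 features were called for TW LD minus ED and 1 for the interaction from ED to LD. Without both GC LD 3 and GC PO 2, 7440 were called for GC PO minus LD (3330 higher, 4110 lower). Of 43 list calls, 0 remained with an estimated correlation, which allows for genes that move together, and fry called 18 lists, 16 of them among the 43.

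With each array left out in turn, the counts ran from 1 to 1261 for GC LD minus ED, 2114 to 7284 for GC PO minus LD, 0 to 31 for TW LD minus ED, 1331 to 5927 for TW PO minus LD, 0 to 270 and 4219 to 7335 for the interactions from ED to LD and from LD to PO, 13957 to 14626 for GC minus TW and 39 to 46 for the list tests. Signal over background limits the values of dim genes, as 64.3% to 82.5% of the spots on an array were well above background.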

Other observations

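The genes below were picked, and the overlap of the layers was counted, after the values were seen. Several genes rose from LD to PO in both layers. PTGS2 did so (log2 3.91 ± 0.89 SE in GC and 1.75 ± 0.38 SE in TW), as did EDN2 (5.56 and 2.93), the G-protein regulator RGS2 (3.74 and 3.53), IER3 (4.04 and 3.07), NR4A1 (2.44 and 2.19) and the phosphatase DUSP1 (1.87 and 1.89). The chemokine receptor CXCR4 (4.25 and 2.15), the insulin receptor substrate IRS2 (2.69 and 2.61), TLR4 (2.33 and 2.47), SOD2 (2.20 and 1.02) and GPX3 (2.89 and 1.58) rose in both as well. Other genes went opposite ways, each with a called interaction: the proliferation mark MKI67 (−3.72 in GC, 1.24 in TW), the tight junction gene OCLN (−3.42 and 1.00), WT1 (−2.73 and 1.41), the sterol enzyme NSDHL (1.49 and −0.81) and HSD17B4 (1.63 and −0.86). Of 24354 features tested in both layers, 197 rose in both and 204 fell in both, against 128 and 196 for independent layers, while 110 rose in GC and fell in TW (123) and 88 fell in GC and rose in TW (203). Features are not independent, and no test of these overlaps was run.

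Of 4 hedgehog genes, also picked after the values were seen, the ligand gene IHH was 10.4-fold higher in GC than in TW and fell by 4.09 (log2) in GC from LD to PO. Its textbook targets GLI1, PTCH1 and HHIP were higher in TW (−3.22, −1.94 and −1.09, GC minus TW) and fell in TW from LD to PO by 3.99, 1.59 and 1.86. From ED to LD in TW their values were −2.06, −1.94 and −1.52, none of them called over all features. A link between the ligand and its targets was not tested, as the labels do not pair GC and TW samples.

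TW LD arrays lay at 0.70, 0.36, 0.14, 0.15, 0.26, 0.83, 0.12, 0.00 and 0.52 between the ED mean (0) and the PO mean (1). TW PO arrays lay at 1.10, 0.75, 0.90, 0.76 and 1.04. In TW PO minus LD the dimmest of 10 brightness bins had a median change of 0.36 (276 higher, 23 lower) and the brightest −0.22 (63 higher, 299 lower). In GC PO minus LD the same bins had −0.09 (128 and 150) and 0.23 (207 and 172). Deviations of arrays from their group means correlated at a mean r of 0.068 for 15 GC pairs and 0.098 for 19 TW pairs on the same slide, against −0.017 and −0.018 for 60 and 96 pairs on other slides. These correlations are across features, which are not independent replicates.

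The 10 genes named in advance were also compared over both steps at once, PO minus ED, a comparison chosen after the values were seen. Over all features, 10940 of 24762 were called in GC and 7035 of 26896 in TW, so a call is common in this comparison. In GC, STAR was 15.5-fold higher at PO (log2 3.95 ± 1.06 SE, adjusted p = 0.00762), PTGS2 14.1-fold higher (3.82 ± 0.89 SE, 0.00325) and FSHR 13.1-fold lower (−3.71 ± 1.15 SE, 0.0171, 4 of 5 PO arrays well above background). These 3 stayed called under 4 other scalings, with slide as a fixed block and with each array left out. INHBA was lower (−0.90 ± 0.32 SE, 0.0343), and not called without GC PO 1, 2 or 3 or GC ED 1 or 4. The other 6 were not called in GC (adjusted p from 0.187 for CYP19A1 to 0.575 for VEGFA). For CYP19A1 this rests on 1 probe, from which all 9 other probes kept differed in direction from LD to PO (−1.28 to −0.84 against 0.06). In TW only PTGS2 of the 10 was called (1.23 ± 0.43 SE, 0.0406), and with slide as a fixed block it was not (0.0786).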
